A study of Mus musculus with 2 samples.

How the data were processed

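Granulocytes and monocytes had been sorted from the bone marrow of wild-type male C57BL/6 mice, and 1 array was hybridised per cell type, 2 arrays in all. Per the labels, total RNA was prepared with a column kit with DNase digestion, 0.5 µg was amplified linearly from a T7 promoter, and the cRNA carried the dye Cy3. The surface markers and gates of the sort, and the number of mice behind each sample, are not given in the sources used here. Both arrays came from 1 slide and 1 scan, so slide and scan did not differ between the cell types, while no array repeated either cell type.

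Per the file headers, the scans were read by Agilent Feature Extraction 10.5.1.1, which gave for each spot an intensity with the background subtracted and spatial trends removed, on a linear scale and not yet normalised between arrays, with flags for outlier spots, saturation and signal well above background. The authors' deposited value table was on a log2 scale. Set against the scanner intensities, it equalled the log2 processed signal plus 1 constant per array, -0.24 for granulocytes and -0.92 for monocytes, with 100.0% of probes with a single spot within 0.01. Its column medians were 4.80 and 4.80. The rule behind these constants is not given in the sources used here.

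Each array held 45018 spots, of which 43379 were gene spots for 41174 probes, each 60 bases long. Control spots and spots flagged as outliers (143 on the granulocyte array and 103 on the monocyte array) were left out, and saturated spots would have been kept, but 0 were saturated. The value of a spot was log2 of its processed signal minus that array's 75th percentile of it, and the spots of a probe were averaged. The 75th percentile was 339.4 for granulocytes and 620.9 for monocytes, so this scaling moved every difference between the arrays by the same amount. Differences are given as granulocyte minus monocyte on the log2 scale.

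Probes were named through the RefSeq accessions of the mouse assembly GRCm38.p6 without their versions (24338 probes), otherwise by the symbol in the file where it is a current symbol (6286) or a single older one (2418). Of the 41089 probes with values, 8047 stayed unnamed, and 420 listed accessions of several genes. Probe positions are those of the files, in the mouse build mm8. A gene was represented by its probe that was well above background on most arrays, then by the brightest. Among 5389 genes with at least 2 probes above background on both arrays, the median SD between probes was 0.23 on the log2 scale, and 54 genes (1.0%) had probes that differed by 2-fold or more in opposite directions.

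A gene not well above background on 1 array was given a lower bound, written "at least": the bright value minus the higher of the dim array's lowest signal among probes well above background (-5.16 for granulocytes and -6.04 for monocytes) and the dim probe's own value. With 1 array per group there is no estimate of the spread between samples. No test was made and no p-value is given, and genes were counted by a rule of size, at least 4-fold. As a measure of spot noise only, the median SD of repeated spots of a probe was 0.07 on each array on the log2 scale.

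Gene lists were fixed before the data were examined. A list's median difference over members above background on at least 1 array was set beside the medians of 10000 random lists of the same size, matched on mean level in 20 bins. The central 95% of these medians is called the random range, and it describes these 2 arrays alone. The genes named are the 10 each way with the largest measured difference and the 5 each way with the largest lower bound, at or above the 75th percentile on the brighter array and with a name other than a number, then up to 4 members per list with the largest differences, members that differed by 2-fold or more against their list's median, and a fixed set of markers. This rule too was fixed before the data were examined. A few genes that it selects are not reported here, though counts and list medians include them.

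The steps were tested on simulated data: 2 arrays made from the monocyte array's real probes with spot noise of SD 0.1 and 200 genes changed by known amounts, over 15122 genes. Of the 50 genes each changed by log2 3.0, 4.0 and 6.0, 100.0% were called at 4-fold, and 0 of the 50 changed by log2 1.5 and 0 of 14922 unchanged genes were. With noise so far below 4-fold these calls were fixed by the settings. They check the calculation only and give no rate of false calls, since differences between samples were not simulated. Of 100 random lists, 3 lay outside the random range.

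The alternatives were other scalings (the median of probes above background on both arrays, quantile normalisation, none), normexp background correction of the mean and local background intensities with limma 3.58.1 (offset 50), the authors' value table, other filters on dim or saturated probes, other rules for several probes, other sizes and the mean of a list. The normexp offset of 50 was added to every spot, beside median processed signals of 33.5 for granulocytes and 54.6 for monocytes. It therefore shrinks the differences of dim genes by arithmetic, apart from any effect of the background correction itself. Scaling by the spike-in controls, leaving out probes that list several genes, and leaving the stefin genes out of the gelatinase list, were added after seeing the data. As a yardstick for list medians under these alternatives, the SD of the random lists' medians was used, since no replicates exist. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and R 4.3.3.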

Results

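Gene expression was measured in granulocytes and in monocytes sorted from mouse bone marrow, with 1 one-colour array per cell type, and the design compares the 2 cell types with each other. Signal was well above background for 26256 probes (63.9%) and 14635 named genes on the granulocyte array, and for 28032 probes (68.2%) and 15175 named genes on the monocyte array. No replicate check exists for any difference given here, and the number of arrays limits the precision.

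Of the markers fixed for a check of the labels, Ccr2, the chemokine receptor of classical monocytes, was lower in granulocytes (-7.67), as were the fractalkine receptor gene Cx3cr1 (-6.54, and -2.12 by its other probe) and Csf1r, the receptor for the monocyte growth factor M-CSF (-1.56). The sialic acid binding receptor gene Cd33 (4.97), the integrin gene Itgam (2.71), the leukocyte antigen gene Ptprc (1.70), S100a8 (1.69) and S100a9 (1.06) were higher. Mpo was lower in granulocytes (-2.99). Lyz2 (0.95), Lyz1 (0.94) and Ly6c1 (0.96, and -0.01 by its other probe) differed by less than 2-fold, and Lyz1 and Ly6c1 changed sign with quantile normalisation (-0.07 and -0.10), under which S100a9 and Lyz2 gave 0.0. The Lyz1 probe lists 2 genes. Ly6g and Ly6c2 were not analysed here. Among genes used as references, Gapdh (1.52), Actb (1.20) and Ywhaz (1.16) were higher in granulocytes, and Ppia (-1.58) and Hprt (-1.25) were higher in monocytes. Xist gave 0.09 and the Y-linked Eif2s3y 1.47, Ddx3y 0.66, Uty 0.59 and Kdm5d 0.31, with Ddx3y, Uty, Kdm5d, Xist and the reference gene Tbp (0.42) negative without scaling.

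Of 15609 genes above background on at least 1 array, 1333 were at least 4-fold higher in granulocytes and 1623 at least 4-fold higher in monocytes. In granulocytes the largest measured differences were those of Cstdc4, a stefin family gene (9.98), the gelatinase gene Mmp9 (9.65), Stfa2l1 (9.41), the chemokine-like Prok2 (8.95), Scrg1 (8.89), the protease gene Asprv1 (8.81), Stfa2 (8.76), the chitinase-like Chil5 (8.53), Cxcr2 (8.38) and the dehydrogenase gene Dhrs9 (8.32). In monocytes they included those of the fibronectin gene Fn1 (-8.51, and -7.25 by its highest probe), the chemokine gene Ccl2 (-8.36), Ms4a4c (-7.78, and -6.09 by its other probe), Rnd3 (-7.76), Ccr2 (-7.67), the phosphatase gene Ptpro (-7.51), Ms4a6c (-7.46), the coagulation factor gene F13a1 (-7.46) and Ms4a6b (-7.38). Genes not well above background on the dimmer array gave bounds. Ankrd33b was at least 403.6-fold and Mcam at least 399.1-fold higher in granulocytes, followed by Dnah6 (at least 125.7-fold), Bmpr1a (at least 92.5-fold) and Tmem45a2 (at least 92.5-fold). The calcium-dependent protease gene Capn2 was at least 228.0-fold and Ms4a6d at least 219.2-fold higher in monocytes, followed by Stxbp6 (at least 200.6-fold), the scavenger receptor gene Msr1 (at least 166.9-fold) and Mcub (at least 124.9-fold). These bounds hold for scaling to the 75th percentile: without scaling those of Ankrd33b and Mcam were 7.79 and 7.77 on the log2 scale, against 8.66 and 8.64, and after normexp background correction the values of Ankrd33b, Mcam, Capn2 and Ms4a6d were 5.69, 5.56, -5.18 and -4.96. The probes for Stfa2l1 and Ms4a6b list 2 genes each, and stefin genes are close copies of one another, so their values may be shared between family members.

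In the build mm8 the Mmp9 probe lies on chromosome 2 at 164646008 to 164646067, the Cxcr2 probe on chromosome 1 at 74093519 to 74093578, the Ccr2 probe on chromosome 9 at 123957008 to 123957067 and the F13a1 probe on chromosome 13 at 36874811 to 36874870. The Fn1 probe spans 71524056 to 71526293 on chromosome 1, longer than its 60 bases. Exon and UTR annotation of this build was not used here.

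**Figure D1:**
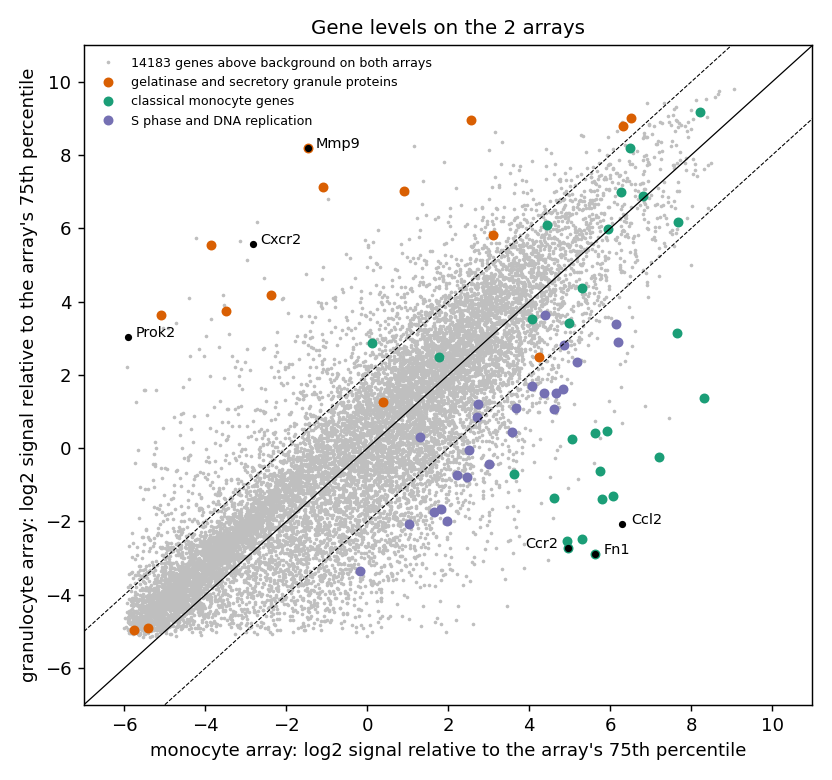
Levels of 14183 genes above background on both arrays, as log2 signal relative to each array's 75th percentile, with monocytes on the horizontal and granulocytes on the vertical axis. The solid line marks equal values, the dashed lines 4-fold, and 3 gene lists are coloured, with Mmp9 at 8.19 in granulocytes against -1.45 in monocytes and Fn1 at -2.88 against 5.63.

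The counts depend on how the arrays are scaled. Across the 14183 genes measured on both arrays the median difference was 0.47, and 50.7% of these genes lay within 2-fold. Across genes, which are not independent replicates, the levels correlated with Pearson's r of 0.86. The 9 spike-in controls used had a median difference of 0.50 after scaling. Granulocytes held 45.1% of the calls at 4-fold, against 16.2% without scaling (581 and 3013 genes) and 25.6% with scaling by the spike-in controls (806 and 2344 genes), which was chosen after seeing the data. After normexp background correction, 872 and 895 genes were counted, with the differences of dim genes shrunk by the offset of 50. All list medians below are therefore given beside their random range, which shifts with any scaling that adds 1 constant.

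Granule protein genes differed by class. Of 9 genes of azurophil granules, the first to form in the granulocyte lineage, 6 were at least 4-fold higher in monocytes, among them Elane (-3.67), Prtn3 (-3.57), Cst7 (-3.47) and Ctsg (-3.40), which apart from Cst7 encode serine proteases. The list's median was -2.99 (random range -0.66 to 1.53), and Serpinb1a (1.98) and Srgn (1.65) went the other way, so that the list's mean was -1.76. Of 16 genes of specific granules, 8 were at least 4-fold higher in granulocytes, with Ceacam10 at 8.11, Olfm4 at 5.60, the collagenase gene Mmp8 at 5.49 and Itgb2l at 4.14, and a median of 1.98 (random range -0.14 to 1.41). Outside the naming rule, Ltf (2.08), Ngp (1.87) and Camp (1.52) differed less. They were bright on the monocyte array too, at log2 levels of 7.33, 6.96 and 7.04 relative to its 75th percentile. The list's median level was 4.62 on the monocyte and 7.67 on the granulocyte array. The ficolin gene Fcnb was higher in monocytes (-1.74). Of the 15 genes listed for gelatinase and secretory granules, 11 were at least 4-fold higher in granulocytes and 0 in monocytes. Mmp9, Stfa2l1, Stfa2 and the formyl peptide receptor gene Fpr1 (8.21) led. The median was 6.11 (random range -0.45 to 1.18), and 4.41 without probes listing several genes. The list fell into 8 genes at 6.11 or above and 7 at 2.71 or below. Without its 3 stefin genes, a choice made after seeing the data, the median of the other 12 was 2.60. Nothing measured here places the products of these stefin genes in such granules, so 6.11 describes the list and not the granules. The gelatinase list shares Fcnb with the specific granule list.

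All 19 genes of the list for the surface and migration of mature neutrophils were higher in granulocytes, 14 of them at least 4-fold, with a median of 4.201 (random range -0.16 to 1.27). Cxcr2, a receptor for neutrophil-attracting chemokines, led it, followed by Fpr1, Retnlg (7.10) and Fpr2 (6.11). The 8 genes of the NADPH oxidase, which makes superoxide, were all above 0, with 3 at least 4-fold higher in granulocytes, a median of 1.73 (random range -0.39 to 1.68), and Ncf1 (2.94), Rac2 (2.41) and Ncf4 (1.81) among the higher values. Of 18 glycolysis genes 4 were at least 4-fold higher in granulocytes and 0 in monocytes, with a median of 1.56 (random range -0.13 to 1.34). They were Hk3 (2.69), Pfkfb4 (2.59), Pfkfb3 (2.24) and the glucose transporter gene Slc2a3 (5.93), whose other probe gave 0.69. The 9 granulocytic transcription factors had a median of 0.55, inside their random range (-0.94 to 1.31) and negative without scaling (-0.32), with Cebpd at 2.07, Spi1 at 1.96 and Cebpa at -1.68. The Lef1 probes went opposite ways (-1.32 and 1.48).

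Classical monocyte genes were higher in monocytes: 17 of 29 by at least 4-fold and 1 (Slfn1, 2.76) the other way, with a median of -4.50 (random range -0.09 to 1.07). Fn1, Ms4a4c, Ccr2 and Ms4a6c led, and Ccl6 (1.70) was higher in granulocytes. Of 18 monocytic transcription factors 10 were at least 4-fold higher in monocytes, with a median of -2.27 (random range -0.39 to 1.12). These included Klf4 (-6.63), Irf8 (-5.46) and Batf3 (-4.18), while Bcl6 (2.89), Nr3c1 (1.37) and Egr1 (1.15) were higher in granulocytes, and the median was -1.23 after normexp correction. The 17 genes of non-classical monocytes were split, with Cx3cr1 and Adgre4 (-5.05) higher in monocytes, Fcgr4 (4.64), Cd9 (3.89), Itgax (2.93, and 1.30 by its other probe) and Treml4 (2.87) higher in granulocytes, and a median of -0.28 inside the random range (-0.67 to 1.04). The 19 macrophage genes had a median of 0.54, inside their random range (-0.33 to 1.03) and negative without scaling (-0.33), from Slc40a1 at 4.65 to Mrc1 at -2.79.

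Of 13 genes of MHC class II presentation, 8 were at least 4-fold higher in monocytes and 0 in granulocytes, with a median of -2.21 (random range -0.98 to 1.05). The cathepsin gene Ctss (-4.50), H2-DMa (-3.48), H2-DMb1 (-2.71) and H2-Aa (-2.52) differed the most, and Cd80 was higher in granulocytes (1.34, and 3.199 by its other probe). Lysosomal hydrolase and cathepsin genes had a median of -0.58 (random range -0.12 to 1.19), with 6 of 25 at least 4-fold higher in monocytes, among them Ctsc (-4.80), Ctss and Lgmn (-4.02), and 3 in granulocytes, which were Ctse (3.11), Ctsd (2.34) and Cd63 (2.14). Among 10 genes of the Fc receptor list, the median was 1.39 (random range -0.63 to 1.36) and the mean 0.43. Besides receptors for antibodies, the list holds Pirb, Pira1 and Pilra, which encode related receptors rather than Fc receptors. Fcgr4 and Pilra (4.30) were higher in granulocytes, and Fcgr1 (-5.99) and Fcgrt (-5.35) were higher in monocytes. Of 40 chemokine, cytokine and receptor genes, 8 were at least 4-fold higher in granulocytes and 11 in monocytes. Cxcr2, the receptor antagonist gene Il1rn (5.73), Il1r2 (5.62) and Il1b (4.59) stood at the one end, and Ccl2, Ccr2, Cx3cr1 and Ccl9 (-5.21) at the other. Their median of -0.19 (random range -0.15 to 0.86) was 0.016 after normexp correction and 0.10 over genes above background on both arrays.

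All 24 genes of S phase and DNA replication were higher in monocytes, 20 of them by at least 4-fold, with a median of -3.02 (random range -0.45 to 0.94). Gins1 (-3.95), the helicase subunit gene Mcm3 (-3.54), the polymerase gene Pola1 (-3.49) and Mcm2 (-3.44) led. Mitosis genes differed less: 2 of 28 reached 4-fold, Bub1b (-2.22) and Aurkb (-2.15), and the median was -1.28 (random range -0.23 to 1.01). Of 19 genes of ribosome biogenesis, 17 were at least 4-fold higher in monocytes, including the methyltransferase gene Fbl (-3.97), Mybbp1a (-3.73), Noc2l (-3.70) and Ddx21 (-3.49, and -1.99 by its highest probe), with a median of -2.87 (random range -0.80 to 0.94). The 39 cytosolic ribosomal protein genes had a median of -1.36 (random range 0.25 to 1.23), with Rpl10a at -3.31 and Rpl3 at -2.95. Oxidative phosphorylation genes had a median of -0.32 (random range -0.02 to 1.20), and 0 of 27 reached 4-fold.

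**Figure D2:**
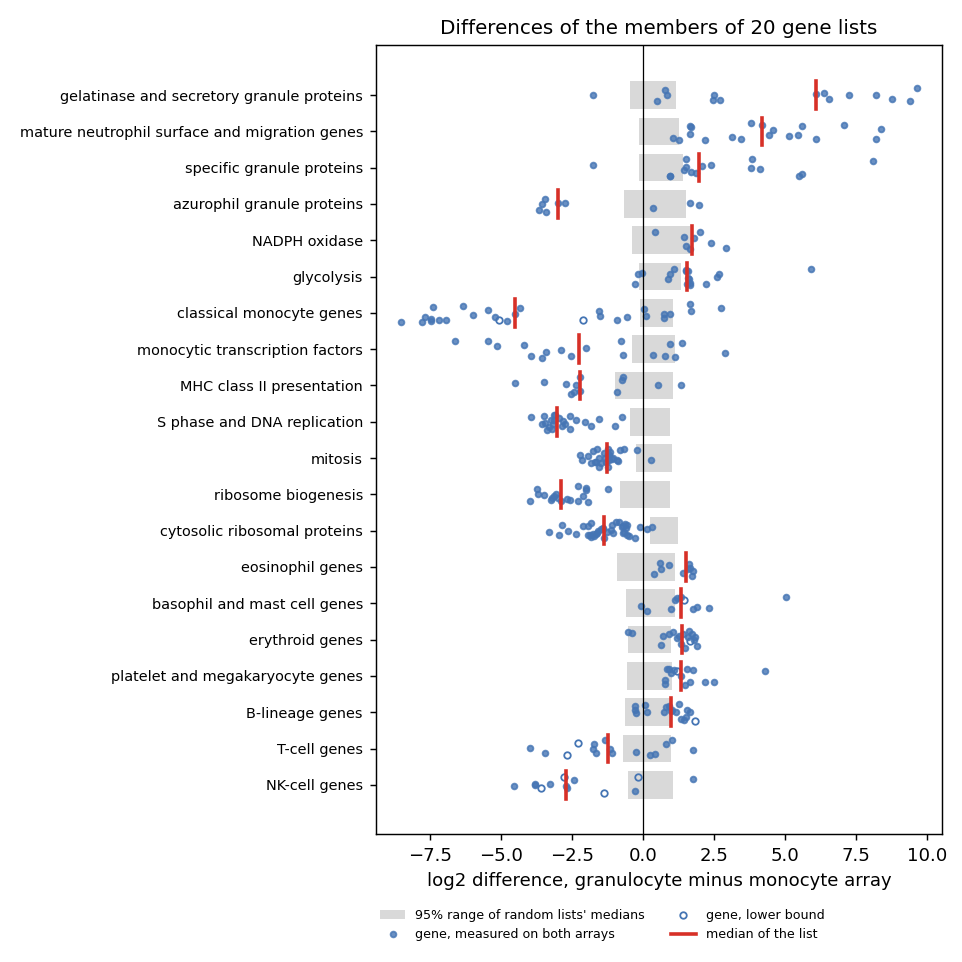
Differences (log2, granulocyte minus monocyte) of the members of 20 gene lists, with 1 point per gene, open points for lower bounds, red bars for list medians and grey bars for the central 95% of medians of random lists. The gelatinase granule list (median 6.11, and 2.60 without stefin genes) and classical monocyte genes (median -4.50) lie at opposite ends, and S phase genes (median -3.02) lie to the left of 0.

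Markers of other bone marrow cells also differed between the arrays. Erythroid genes had a median of 1.37 (random range -0.53 to 0.98), and the haemoglobin genes Hba-a1 (1.92, by a probe that lists 2 genes) and Hbb-bt (1.78) and the haem synthesis gene Alas2 (1.83) were among the highest. Platelet and megakaryocyte genes had a median of 1.33 (random range -0.57 to 1.03), led by Clec1b (4.32) and Gp9 (2.52), with the Itgb3 probes at 2.19 and 0.47. Eosinophil genes (median 1.5, random range -0.92 to 1.13), with Ear10 at 1.78 by a probe that lists 2 genes and Ear1 at 1.72, and basophil and mast cell genes (median 1.35, random range -0.59 to 1.14), with the histidine decarboxylase gene Hdc at 5.03 and Cpa3 at 2.35, lay above their random ranges as well. B-lineage genes had a median of 1.001 (random range -0.62 to 0.96), and 0 of 18 reached 4-fold. Cd79b (-0.28) and Ighm (-0.24, and -1.91 by its lowest probe) were below 0. The stem and progenitor list (median 0.72, random range -0.49 to 1.03, negative without scaling at -0.16) and the stromal and endothelial list (median 0.99, random range -0.18 to 1.08) were inside their ranges, with Cd34 (-3.51) and Cd27 (-3.19) higher in monocytes and Erg (3.18) and Col1a1 (3.95, with its lowest probe at 0.57) in granulocytes. NK-cell genes were higher in monocytes (9 of 13 by at least 4-fold, median -2.73, random range -0.53 to 1.06), among them Klrd1 (-4.53), Txk (-3.82) and Ccl5 (-3.82), while Gzma gave -0.26 and Klre1 was higher in granulocytes (1.75). T-cell genes (median -1.23, random range -0.69 to 0.98) included Lck (-3.98) and Cd3g (-3.44) at the monocyte side and Cd3d (1.76) at the other. Plasmacytoid dendritic cell genes (median -1.96, random range -1.002 to 1.04) and, by little, dendritic cell genes (median -0.98, random range -0.89 to 1.04, with 5 of 12 genes at least 4-fold higher in monocytes) lay below their random ranges, with Siglech at least 15.6-fold higher in monocytes, Clec10a at -6.15, and Itgax, Runx2 (1.83) and Xcr1 (1.20) higher in granulocytes. Probes went opposite ways for Pacsin1 (-3.06 and 0.65) and for Klk1 (1.09, by a probe that lists 4 genes, and -2.34). After normexp correction the medians of the NK-cell, T-cell, plasmacytoid and dendritic cell lists were -1.29, -0.39, -1.33 and -0.17, the last inside its random range there (-0.29 to 0.84). As a level for genes of other tissues, chosen after seeing the data, 604 sensory receptor and keratin genes above background had a median of 0.90.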

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

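The spike-in scaling, the restriction to probes that list 1 gene and the gelatinase list without stefin genes were chosen after seeing the data. With 1 array per group the alternatives move values between settings and say nothing of the spread between mice. Counts of genes at least 4-fold higher in granulocytes became 581 without scaling, 872 after normexp correction and 806 with spike-in scaling, and those in monocytes became 3013 without scaling and 895 after normexp correction. At 2-fold they were 4538 and 3258, and at 8-fold 522 and 667, by construction. Under the other alternatives both counts stayed within 1.5 times. Of the 234 genes the naming rule selects, 144 had a difference of at least 4-fold, and they kept their direction in all 1708 values computed, for 124 of them under 12 alternatives and for 20 under 11, since bounds and probes that list several genes drop out of 1. Scalings that add 1 constant could not reverse such a difference: the largest shift, without scaling, was -0.87, against log2 2.0 for 4-fold. Filters that keep a gene's probe could not reverse it either. For those alternatives the kept direction was fixed in advance. Of the 533 list medians recomputed over 38 lists, 424 moved by less than the SD of their random lists' medians. Part of that count was fixed in advance. Leaving out saturated probes could move no median, nor could filters on dim probes for lists with every member measured on both arrays. Among the 26 lists outside their random range, only that of chemokines, cytokines and their receptors changed sign, to 0.016 after normexp correction and to 0.10 over genes above background on both arrays. Of the 12 lists inside their range, 9 changed sign under at least 1 alternative, 25 times in all. The cause was not tested, except that the median, spike-in and absent scalings and the authors' table differ from the main one by 1 constant, unlike quantile normalisation. Leaving out saturated probes changed nothing because 0 spots were saturated. Dim genes are limited by signal over background: the lowest signals well above background lay at -5.16 and -6.04.

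Without scaling, the granule list medians were -3.86 (azurophil), 1.105 (specific) and 5.24 (gelatinase), and those of the other lists were 3.33 for mature neutrophil genes, -0.32 for granulocytic and -3.14 for monocytic transcription factors, -5.37 for classical and -1.15 for non-classical monocyte genes, -0.33 for macrophage genes, -3.08 for MHC class II, -0.36 for MHC class I, -1.85 for dendritic and -2.83 for plasmacytoid dendritic cells, 0.63 for eosinophils, 0.48 for basophils, 0.13 for B-lineage, -2.11 for T-cell, -3.60 for NK-cell, 0.50 for erythroid and 0.45 for platelet genes. They were -0.16 for stem, 0.12 for stromal, -3.89 for S phase, -2.15 for mitosis, -2.23 for ribosomal protein, -3.74 for ribosome biogenesis, -1.20 for oxidative phosphorylation, 0.69 for glycolysis, -0.79 for cholesterol synthesis, 0.86 for NADPH oxidase, -0.037 for pattern recognition, 0.52 for Fc receptor, -1.06 for chemokine and cytokine, -0.47 for interferon-stimulated, -0.85 for immediate early, -1.46 for lysosomal, 0.18 for integrin and 0.071 for label check genes.

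Spike-in scaling gave 1.48 for specific and 5.61 for gelatinase granules, 3.70 for mature neutrophil genes, -2.76 for monocytic transcription factors, -4.999 for classical and -0.77 for non-classical monocyte genes, 0.044 for macrophage genes, 0.019 for MHC class I, -1.48 for dendritic cells, 0.85 for basophils, 0.50 for B-lineage, -1.73 for T-cell, -3.22 for NK-cell, 0.87 for erythroid and 0.83 for platelet genes. It gave 0.22 for stem, 0.49 for stromal, -3.52 for S phase, -1.78 for mitosis, -1.85 for ribosomal protein, -3.37 for ribosome biogenesis, -0.82 for oxidative phosphorylation, 1.07 for glycolysis, -0.41 for cholesterol synthesis, 0.34 for pattern recognition, -0.69 for chemokine and cytokine, -0.10 for interferon-stimulated, -0.47 for immediate early, -1.08 for lysosomal, 0.56 for integrin and 0.45 for label check genes. Quantile normalisation gave -3.60 for azurophil and 1.16 for specific granules, -5.09 for classical monocyte, 0.08 for macrophage, -0.06 for MHC class I, -1.71 for mitosis, -1.86 for ribosomal protein, -0.88 for oxidative phosphorylation, 0.94 for glycolysis, 1.18 for NADPH oxidase, 0.014 for interferon-stimulated, -0.55 for immediate early, -0.97 for lysosomal, 0.54 for integrin and 0.28 for label check genes.

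Normexp correction gave -1.23 for monocytic transcription factors, -4.06 for classical monocyte, -0.17 for dendritic cell, -1.33 for plasmacytoid, -0.39 for T-cell, -1.29 for NK-cell and -2.14 for ribosome biogenesis genes. Its offset shrinks dim differences, so these moves cannot be put down to background correction alone. Means in place of medians gave -1.76 for azurophil, 2.73 for specific and 4.69 for gelatinase granules, -1.87 for monocytic transcription factors, -3.45 for classical monocyte, 0.09 for macrophage, -2.29 for NK-cell, 0.31 for stem, 0.43 for Fc receptor, -0.36 for interferon-stimulated, -0.42 for immediate early and 0.035 for label check genes. The gelatinase median was 4.41 over probes that list 1 gene and 2.60 without stefin genes, the macrophage median -0.53 with all probes of a gene averaged, and the dendritic cell median -0.40 over genes above background on both arrays.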

Other observations

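Of the tests below, that against the sensory receptor and keratin genes was set before its result was seen, and the others were chosen only after.

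Interferon-stimulated genes went both ways, with a median of 0.40 in the middle of their random range (-0.25 to 0.95), negative without scaling (-0.47) and with the list's mean at -0.36. Of 31 genes, 18 differed by less than 4-fold and 7 were at least 4-fold higher in monocytes, among them the antiviral GTPase genes Mx1 (at least 119.9-fold) and Mx2 (-5.32), Ifi203 (-5.44, and -4.19 by its other probe) and Gbp3 (-4.65). In granulocytes 6 were at least 4-fold higher: Rsad2 (2.95), Oas3 (2.93, and 1.07 by its other probe), Rtp4 (2.56), the RNA sensor gene Ddx58 (2.27), Ifit1 (2.23) and Oas2 (2.11). Pattern recognition receptor genes had a median of 0.84 inside their random range (-0.46 to 1.02), which was -0.04 without scaling, with the lectin receptor genes Clec4d (6.00) and Clec4e (3.01) and the flagellin receptor gene Tlr5 (3.16) higher in granulocytes and Tlr1 (-2.09) higher in monocytes. The 19 immediate early and heat shock genes lay around 0 (median 0.02, random range -0.13 to 1.35, and -0.85 without scaling), but the chaperone genes Hspa1a (-5.72) and Hsph1 (-3.77) and the stress factor gene Atf3 (-3.95) were higher in monocytes.

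Integrin and adhesion genes had a median of 1.06, inside their random range (-0.44 to 1.097), with Ceacam10 (8.11), Cd9 (3.89) and Itgax (2.93, and 1.30 by its other probe) higher in granulocytes and Itgb7 (-3.77), Icam1 (-2.93), Itga5 (-2.79) and Vcam1 (-1.52) higher in monocytes, while probes went both ways for Itgb1 (-1.68 to 0.47) and Itga4 (-2.25 to 0.54). MHC class I presentation genes had a median of 0.52 (random range -0.32 to 1.54), negative without scaling (-0.36), with the immunoproteasome gene Psmb10 at -2.25. Cholesterol synthesis genes had a median of 0.08 (random range -0.75 to 0.98), negative without scaling (-0.79), with Insig1 at -2.16 and Dhcr7 at -1.90. The 23 label check markers had a median of 0.94 (random range -0.17 to 1.15).

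Erythroid, platelet, eosinophil and basophil genes lay higher on the granulocyte array. Signal of genes that neither cell type expresses is 1 explanation. As the cause, it would put the median of markers of similar level inside level-matched draws from 604 sensory receptor and keratin genes. These draws had a range of 0.68 to 1.07, and the 32 markers had a median of 1.19, above it by little. The rule, set beforehand, was thus not met for such signal as the whole cause. Such signal may account for part of the pattern. A lower share of sorted cells on the granulocyte array would raise the markers of all other types. The B-lineage median (1.001) lay above its random range (-0.62 to 0.96), also after normexp correction (0.835, range -0.19 to 0.80). The stromal median (0.99) lay inside its range (-0.18 to 1.08). Both medians lay near the 0.90 of the 604 receptor and keratin genes, and no level-matched draws were made for these lists. Signal of genes that neither cell type expresses was therefore not set apart for them. The T-cell (-1.23), NK-cell (-2.73) and plasmacytoid (-1.96) medians lay below their random ranges, also after normexp correction (-0.39, -1.29 and -1.33). Each value is a difference between the arrays, so more RNA of a cell type on the monocyte array would lower it too. These medians therefore cannot decide whether the share of sorted cells differed. More RNA from the erythroid, platelet, eosinophil and basophil types on the granulocyte array stays open. The 21 brighter markers had a median of 1.66 (range of level-matched random lists -0.74 to 0.92), which restates the pattern. Of these markers 2, Tfrc (-0.51) and Tspan33 (-0.40, and 0.24 by its other probe), lay below the random median of 0.15. Eosinophils and basophils are themselves granulocytes, neutrophils also express Hdc and Clec1b, and no gate is known here that would remove the other cells.

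The granule lists had different medians, -2.99 for azurophil, 1.98 for specific and 6.11 for gelatinase granules, but the last was 2.60 without stefin genes, so an order of specific and gelatinase granules is not shown. Granulocytes of the make-up of the granulocyte sort among the monocytes, at the share that the specific granule median needs, would hold every granulocyte gene's difference near 1.98 or below, and 10 of 18 mature neutrophil genes outside that list (55.6%) exceeded it by more than the 0.71 and 0.78 that the lists' random ranges reach to each side, added together. Linearity was not measured for the brightest gene spots, which lay above the brightest spike-in control. Over members dimmer than that control, the specific granule median exceeded the azurophil median by 5.12. This kept 9 of 9 azurophil and 14 of 16 specific members, so the gap could hardly have changed. The differences of the 2 brightest controls exceeded those of the next 5 by at most 0.26. These values cannot decide whether loss of linearity altered the gap. Cells at an earlier granulocytic stage in the monocyte sort, or monocyte precursors that share azurophil genes, may account for the azurophil median of -2.99 beside the S phase median of -3.02, and these cannot be told apart here, since the monocytic transcription factors were also higher. A biological difference between the sorted cell types stays open too.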
